A study of Mus musculus with 12 samples.

How the data were processed

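Total RNA (500 ng per sample) from whole hearts of CD1 mice was labelled as biotinylated cRNA and hybridized to Affymetrix 3′ arrays, per the labels' protocols. Hearts were from DN-MCU mice and WT littermates at 42 days, all labelled male, and at 1 day, with no sex given. Each of the 4 groups had 3 arrays. The values were deposited by the authors as 1 table of log2 signals already normalized between arrays; the log2 scale was inferred from the values, and the normalization algorithm is not given in the sources used here. Partek is named in the submitters' processing notes, with no version and no stated role. The table held 45101 probe sets, of which 34945 were annotated with 1 gene, 932 with several and 9160 with none. Gene IDs of 34754 probe sets were matched to the reference gene table, which changed 0 symbols. Mcub was not analysed here.

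Everything else was computed from that table, with no further normalization. The 64 control probe sets were removed. A probe set was kept if the third highest of its 12 values was above the median of all values (log2 3.35), which left 24176: 20783 with 1 gene, 590 with several and 2803 with none. Signals below that level are close to background, so changes of dim transcripts are measured least well. Group means of all 12 arrays were fitted with limma 3.58.1 in R 4.3.3, with moderated statistics and Benjamini-Hochberg adjustment within each comparison, and a probe set passed at an adjusted p under 0.05. The comparisons were DN-MCU against WT in adults, the same in neonates, the difference of these effects, their average, and WT neonates against WT adults. The p values measure spread between separately labelled animals, and with 3 animals per group they have low precision. Values after ± are SD, and the SE of a log2 difference comes from the fit. In the weighing of patterns, an SE comes from the spread of the arrays compared. For a list median it is the SE of the same contrast on each array's mean over members, not of the median itself.

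For gene lists, each gene was represented by the probe set with the highest mean over all arrays (11807 genes). Of 37 lists fixed, the 33 pathway and cell type lists with at least 5 measured members were tested with camera at a preset inter-gene correlation of 0.01, again with Benjamini-Hochberg adjustment. Each was also tested with a correlation estimated per list and with fry, and single members were also adjusted over their list alone. Some lists share genes, so the calls of lists are not independent. The comparisons, tests, filter, lists, naming rule and most alternatives were chosen before the data were examined.

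Genes named in the text follow a rule. Among genes that passed with no overlap between groups, it names the 10 largest changes in each direction, filled with the smallest p values up to 5 where fewer passed. For the difference of effects it names the 5 smallest p values per direction. It adds the 4 members with the smallest p of each list that passed, and Mcu, its partners and a set of cardiac genes in every case. Not every gene under the rule is printed, and Ghitm, Gyg, Hk1 and Pgam1 were named outside it after their values were seen. A probe set with no gene or several genes is not named, and a gene whose other probe sets have the opposite sign is named with that said.

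Whether the replicate numbers pair arrays was checked by correlating deviations from group means before the calls of the fits were compared. For neonates the same-numbered WT and DN-MCU arrays correlated at 0.133, 0.223 and 0.283, all above 0.1, so the numbers were taken to pair them; the labels do not say what a number stands for. A fit with the replicate number of the neonates as a block was therefore added after the data were seen, and its values stand beside the results it changes. In the adult comparison this block leaves every difference as it was. It acts there only through the spread shared by all groups and the degrees of freedom.

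The fit was tested on simulated data with 200 of 24176 probe sets changed. This was first run with 1 simulation and then raised to 10 because the share of false calls was noisy. With 1 spread for all groups, 32.4% of probe sets changed by a log2 of 1 and 76.8% of those changed by 2 were recovered in the adult comparison, and 5.45% of calls were false. For neonates these were 33.3%, 75.7% and 5.79%. With each group's own spread, 72.3% of adult and 11.7% of neonatal calls were false when all 12 arrays were fitted, and 10.5% of each when only the groups compared were fitted. In that last fit 5.9% and 43.8% of adult changes of 1 and 2 were recovered. In a simulated list test over 11807 genes in the adult comparison the moved list passed and 0 of 32 others did. Genes were drawn independently there, so it does not show how often lists of correlated genes pass by chance.

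Alternatives tried were quantile normalization, subtraction of array medians, no filter and a stricter filter (log2 7.25), leaving out cross-matching probe sets, 1 probe set per gene and other thresholds. Further ones were an ordinary linear model without moderation, limma with trend and robust settings, array weights, the replicate number as a block, the range of adult animal numbers as a term, only the groups compared, and each array left out in turn. Added after the data were seen were the fit without the 2 arrays of lowest weight (DN-MCU adult 3, 0.0728, and WT adult 1, 0.251), the Xist signal of neonates or the spike control signal as a covariate, the neonatal block, leaving out the pair of adults whose animal numbers lie in a separate, lower range, and the fit of only the groups compared for lists and named genes. Counts were also taken for other splits of the same arrays into groups of the same sizes. For adults, neonates and age every other split was used. For the difference and the average 100 splits were used, the real one and others drawn at random.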

Results

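Whole hearts of CD1 mice, an outbred stock, were profiled on Affymetrix expression arrays with 500 ng of total RNA per sample. The mice expressed a dominant-negative form of MCU, the pore-forming subunit of the channel that admits calcium into mitochondria, or were wild-type (WT) littermates. Hearts were taken at 1 day and at 42 days of age. Each of the 4 groups, WT adult, DN-MCU adult, WT neonate and DN-MCU neonate, held 3 arrays. All values are log2 signals, with array medians between 3.24 and 3.46. The number of arrays limits the precision of every comparison.

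The 2 ages lay far apart on the first principal component, which held 71.7% of the variance over the 24176 probe sets analysed. The neonatal arrays were close to each other, with mean correlations to their own group between 0.991 and 0.993. Adult arrays were more scattered. DN-MCU adult 3 lay at 121.4 on the second component (13% of the variance), where the other 11 arrays lay between -50.89 and 24.42, and its mean correlation with the other DN-MCU adults was 0.931. Its adipocyte markers averaged -2.40 on the log2 scale relative to the other DN-MCU adults, and its erythroid markers lay 0.93 above them. Its spiked controls averaged 11.72, against 11.14 to 11.37 in the other adults. WT adult 1 held epicardial and mesothelial markers 1.25 above the other WT adults and adipocyte markers 0.79 above them. The upper quartile of signals was 6.987 in DN-MCU adult 3 and 7.045 in WT adult 1, against 7.154 or more in the other adults. Deviations of these 2 arrays from their group means correlated at 0.579. Whether their scatter is technical or reflects the tissue taken was not tested. The median standard deviation (SD) of a probe set was 0.226 in WT adults, 0.400 in DN-MCU adults, 0.132 in WT neonates and 0.141 in DN-MCU neonates.

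**Figure D1:**
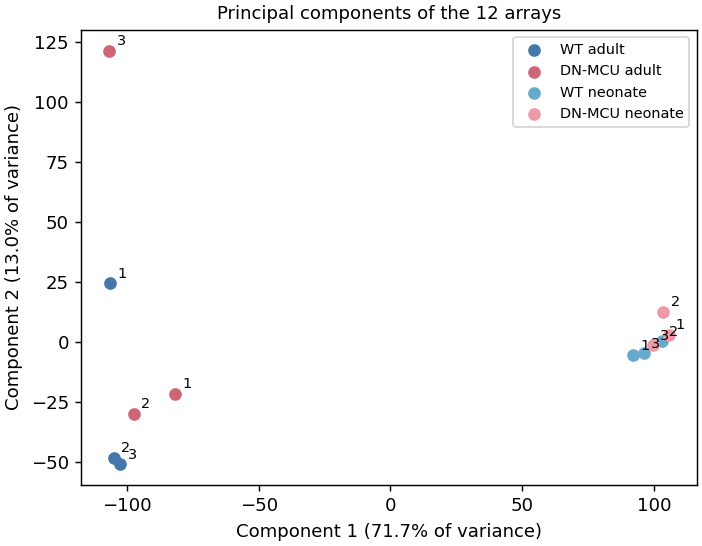
Scores of the 12 arrays on the first 2 principal components of the 24176 probe sets analysed (axes in component units, with the percent of variance), coloured by group and numbered by replicate. Adult and neonatal arrays part on component 1 (71.7%), and DN-MCU adult 3 stands alone at 121.4 on component 2.

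Mcu itself was read by 2 probe sets that behaved differently. The dimmer of them in WT hearts was 3.35 ± 1.08 (SD, n = 3) in WT adults and 9.64 ± 0.78 in DN-MCU adults, a log2 difference of 6.28 (standard error, SE, 0.52; limma adjusted p = 8.94e-05). In neonates it was 3.15 ± 0.22 in WT and 8.82 ± 0.43 in DN-MCU hearts, a log2 difference of 5.67 (SE 0.52, adjusted p = 0.0101). Its WT levels lie at or under the level of the filter on dim probe sets (3.35), near background. No fold is therefore given, and the rises at the 2 ages are not compared. Every one of the 6 DN-MCU arrays, at 8.44 or more, exceeded every WT array, at 4.55 or less, in accord with the genotype labels. The neonatal call was lost without DN-MCU neonate 1 (adjusted p = 0.0551), without WT neonate 2 (0.0949) and with the neonatal replicate number as a block (0.0717), while the difference itself stayed between 5.43 and 5.85 without any 1 neonatal array. The other probe set, between 7.39 and 8.18 in every array, did not change in adults (0.03, SE 0.21, adjusted p = 0.963) or neonates (0.04, SE 0.21, adjusted p = 1). Which part of the transcript each probe set matches, and whether it sees the transgene or the native gene, is not given in the sources used here.

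**Figure D2:**
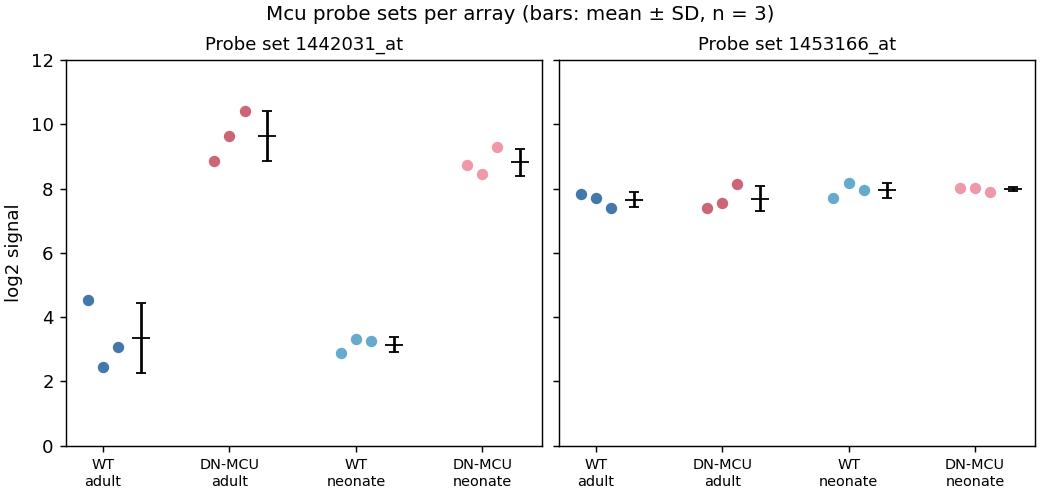
Log2 signal of both Mcu probe sets in each of the 12 arrays, by group, with the mean ± SD of 3 arrays beside the points. One probe set lies at or above 8.44 in all DN-MCU arrays and at or below 4.55 in all WT arrays, while the other lies between 7.39 and 8.18 in every array.

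The first comparison asked what changed in adult hearts expressing DN-MCU. Genes of the integrated stress and mitochondrial stress list rose strongly. Mthfd2, a mitochondrial folate enzyme, rose from 4.49 ± 0.44 to 11.69 ± 0.35 (SD, n = 3), a log2 difference of 7.20 (SE 0.34) or 147-fold. Asns, asparagine synthetase, rose 93.6-fold (6.55, SE 0.40), and Slc7a5, a transporter of large neutral amino acids, 65.4-fold (6.03, SE 0.35). Phgdh and Psat1, which act in sequence in serine synthesis, rose by 4.91 (SE 0.33) and 3.76 (SE 0.22). Trib3, a pseudokinase of the stress response, rose by 6.06 (SE 0.43), and Fgf21, which encodes a secreted metabolic hormone, by 6.21 (SE 0.54). The largest adjusted p among these 7 genes was 0.000133. Of the 34 measured members of the integrated stress and mitochondrial stress list, 20 rose and 14 did not pass; adjusted over the list alone, 22 rose and 1 fell. The list's median change was 1.52 (camera adjusted p = 1.5e-22; adjusted p = 0.0554 with an estimated correlation), and it was 1.53 without DN-MCU adult 3.

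Among the other genes with the largest rises were Brca2 (6.10, SE 0.32), a gene of DNA repair by homologous recombination, Shisa3 (5.16, SE 0.17), Stbd1 (4.76, SE 1.06), a glycogen-binding protein, and Avil (4.59, SE 0.22), an actin-binding protein. The largest falls included Myot (-4.07, SE 0.79), a protein of the sarcomeric Z-disc, Hamp (-3.48, SE 0.42), which encodes the iron hormone hepcidin, and Scn4b (-3.09, SE 0.34), an auxiliary subunit of voltage-gated sodium channels. Gpr22, Smco1, Pdzd3, Efnb3, Scube2, Lgi1 and Plekhh1 fell by between -2.76 and -3.25. The fold change of a gene whose lower group lay under a log2 signal of 3.35, the level of the filter, is measured against signal near background: this applies to Fgf21 (1.86 in WT adults), Brca2 (3.06), Avil (2.48), Vgll2 (2.68), Pdzd3 (2.49 in DN-MCU adults) and Lgi1 (3.04). Of the 54 genes named for adults that passed, 14 kept the call when the adult arrays were fitted alone, namely Mthfd2, Asns, Fgf21, Brca2, Trib3, Slc7a5, Shisa3, Phgdh, Avil, Hamp, Pdzd3, Psat1, Myc and Gyg. Stbd1 (adjusted p = 0.29), Myot (0.234), Gpr22 (0.341), Smco1 (0.267), Scn4b (0.0652), Efnb3 (0.219), Scube2 (0.289), Lgi1 (0.0989) and Plekhh1 (0.28) did not. With the replicate number of the neonates as a block, Stbd1 (adjusted p = 0.083), Myot (0.0553), Gpr22 (0.118), Smco1 (0.0697), Scube2 (0.0806) and Plekhh1 (0.0783) also lost the call. Adult differences are unchanged by this block, which acts on them only through the shared spread and the degrees of freedom.

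The lists of mitochondrial energy metabolism had medians below 0, mostly small. Of 47 measured members of the fatty acid uptake and oxidation list, 6 fell, 1 rose and 40 did not pass, and 17 fell and 2 rose adjusted over the list alone. Its median was -0.48 (camera adjusted p = 5.23e-09; adjusted p = 0.0941 with an estimated correlation). Hadha, a subunit of the mitochondrial trifunctional protein, fell by 0.72 on the log2 scale (SE 0.13), the peroxisomal enzyme Ehhadh by 1.09 (SE 0.21) and the acyl-CoA thioesterase Acot1 by 1.87 (SE 0.35), whereas the thioesterase Acot2 rose by 1.00 (SE 0.19). The tricarboxylic acid cycle list (25 members) had a median of -0.25 (adjusted p = 0.00118; adjusted p = 0.148 with an estimated correlation), although the 1 member that passed, malic enzyme Me2, rose (0.85, SE 0.18). None of 32 complex I subunits and none of 13 genes of pyruvate entry passed singly in limma, and adjusted over the list alone 0 and 1 fell. Their medians were -0.19 (camera adjusted p = 0.000189) and -0.43 (0.00244), with adjusted p = 0.388 and 0.211 with an estimated correlation. As fixed, the pyruvate and tricarboxylic acid cycle lists share Pdha1, Pdhb, Dlat, Pdhx and Dld, so these calls are not independent. The list of 43 subunits of complexes II to V had a median of -0.10 (adjusted p = 0.0106; adjusted p = 0.413 with an estimated correlation), against which Cox8a (1.10, SE 0.20), Cox6a1 (0.73, SE 0.13) and Atpif1 (0.65, SE 0.14), an inhibitor of ATP synthase, rose. Adjusted over the list alone, 3 of these subunits rose and 2 fell. Without DN-MCU adult 3 the median of the pyruvate list was -0.28 (adjusted p = 0.0171), and without DN-MCU adult 1 the list of complexes II to V did not pass (adjusted p = 0.124). With the neonatal replicate block Ehhadh (adjusted p = 0.0503), Me2 (0.0614) and Atpif1 (0.0746) did not pass. With the adults fitted alone, no member of these 5 lists passed over all probe sets (limma; 2500 of all probe sets had an unadjusted p under 0.05). The glycolysis and glucose uptake list (32 members) did not pass (median 0.07, camera adjusted p = 0.934). In it Gyg, which primes glycogen synthesis (1.46, SE 0.14), and the glycolytic enzymes Hk1 (1.08, SE 0.22) and Pgam1 (1.07, SE 0.14) rose and none fell, or 5 and 6 adjusted over the list alone; these 3 were named after their values were seen, and with the adults alone only Gyg passed.

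Calcium handling and contractile genes also moved lower as lists. Of 51 genes of cytosolic calcium handling, 1 rose and 2 fell, or 2 and 5 adjusted over the list alone, and the median was -0.28 (adjusted p = 0.000377; adjusted p = 0.0554 with an estimated correlation). The calcium buffer Casq1 fell by 2.38 on the log2 scale (SE 0.53), the T-type calcium channel Cacna1g by 1.86 (SE 0.45), and Fkbp1b, which binds the ryanodine receptor, rose by 0.82 (SE 0.15). Hrc, which binds calcium in the sarcoplasmic reticulum, was lower by a log2 difference of -1.04 (SE 0.27) that did not pass (adjusted p = 0.0519). Of 25 sarcomere genes, Myot and Tcap (-0.65, SE 0.16) fell, also adjusted over the list alone, with a list median of -0.12 (adjusted p = 0.00721; adjusted p = 0.388 with an estimated correlation). With the neonatal replicate block Casq1 (adjusted p = 0.0841), Cacna1g (0.101) and Tcap (0.0796) did not pass. In the list of 22 ion channel genes Kcnj3 fell (-1.72, SE 0.36), 3 fell adjusted over the list alone, and the median was -0.12 (adjusted p = 0.0347; adjusted p = 0.211 with an estimated correlation). None of 17 endothelial markers passed in limma (1 fell adjusted over the list alone) and their median was -0.27 (camera adjusted p = 0.0032; adjusted p = 0.119 with an estimated correlation). Without DN-MCU adult 3 the median was -0.16 for calcium handling and -0.28 for ion channels. The ion channel list had a median of -0.19 without WT adult 2 and did not pass without DN-MCU adult 1 (adjusted p = 0.186), DN-MCU adult 2 (0.0751) or WT adult 1 (0.156). The uniporter's partners Micu2 (0.08, SE 0.55), Micu3 (-0.37, SE 0.47) and Smdt1 (0.10, SE 0.15) and the mitochondrial sodium-calcium exchanger Slc8b1 (-0.26, SE 0.21) did not pass. In their list of 21 genes of mitochondrial calcium transport 1 rose, Ghitm (0.93, SE 0.19), which was singled out after its value was seen; 1 rose and 1 fell adjusted over the list alone, and the list did not pass (camera adjusted p = 0.748). Ghitm did not pass with the neonatal replicate block (adjusted p = 0.057), and with the adults fitted alone no member of any of these 5 lists did.

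Other stress and growth lists were higher. Of 21 genes of endoplasmic reticulum stress, Ern1 (1.34, SE 0.18), Atf6 (0.91, SE 0.14) and Sel1l (0.53, SE 0.13) rose and none fell, 6 rose adjusted over the list alone, and the median was 0.25 (adjusted p = 0.00141; adjusted p = 0.0554 with an estimated correlation). In the list of 26 immediate early genes Myc (2.46, SE 0.19) and Atf3 (1.62, SE 0.41) rose and Nr4a3 fell (-1.71, SE 0.40), 5 rose and 1 fell adjusted over the list alone, and the median was 0.47 (adjusted p = 0.00053; adjusted p = 0.388 with an estimated correlation). Among 31 antioxidant genes 5 rose and 1 fell, or 7 and 4 adjusted over the list alone. Gss (1.14, SE 0.17) and Gclm (0.61, SE 0.13) of glutathione synthesis and Srxn1 (1.21, SE 0.19) rose and the quinone reductase Nqo1 fell (-1.08, SE 0.14). That list's median was 0.33 (adjusted p = 0.0347; adjusted p = 0.413 with an estimated correlation). Of 22 genes of hypertrophy and the fetal programme 5 rose, or 6 with 2 falls adjusted over the list alone, and the median was 0.24 (adjusted p = 0.0431; adjusted p = 0.413 with an estimated correlation). These included smooth muscle actin Acta2 (1.69, SE 0.21), Ccn2 (1.53, SE 0.31), Vgll2 (3.69, SE 0.81) and Nppb, brain natriuretic peptide (1.27, SE 0.30, adjusted p = 0.0403). With the neonatal replicate block Sel1l (adjusted p = 0.113), Atf3 (0.106), Nr4a3 (0.0805), Gclm (0.0695) and Vgll2 (0.083) did not pass. The antioxidant list did not pass without DN-MCU adult 2 (adjusted p = 0.114), DN-MCU adult 3 (0.221), WT adult 2 (0.0532) or WT adult 3 (0.0709). The hypertrophy list did not pass without DN-MCU adults 1, 2 or 3 (0.0582, 0.0568 and 0.328) or WT adults 1 or 2 (0.136 and 0.0532), nor the immediate early list without DN-MCU adult 2 (0.0892). Nppa (0.34, SE 0.16), Myh6 (-0.02, SE 0.11), Myh7 (0.20, SE 0.50), Atp2a2 (-0.05, SE 0.11) and Pdk4 (-0.18, SE 0.24) did not pass. In the cell cycle list of 42 genes Ccnd2 rose (2.03, SE 0.28) and Ccne1 fell (-1.19, SE 0.25, with other probe sets of the gene of opposite sign), also adjusted over the list alone. The median of that list was 0.52 (adjusted p = 0.0158; adjusted p = 0.69 with an estimated correlation). Without DN-MCU adult 1 its median was 0.00178 (adjusted p = 0.947), without DN-MCU adult 2 it was 0.79, and without WT adult 3 the list did not pass (adjusted p = 0.0628). With the adults fitted alone, 1 immediate early gene, Myc, rose and no member of the other 4 lists of this paragraph passed.

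In all, 1152 of 24176 probe sets passed in adults at an adjusted p under 0.05 in limma, 681 higher in DN-MCU hearts (486 genes) and 471 lower (293 genes), and 746 of them changed at least 2-fold; 17.2% of all probe sets showed no overlap between the groups' arrays, where chance gives 10%. This count assumes 1 spread for all groups. With the adult arrays fitted alone the count was 112 (94 higher, 18 lower), with 13 of the 34 stress list members higher. Simulated data had each group's own spread and 200 changed probe sets. There the fit over 12 arrays made 495 calls on average, 357.9 of them false (72.3%). For adults fitted alone 5.8 of 55.5 calls were false (10.5%). These shares hold for that number of changed probe sets and not for the 1152. They also take SDs of 3 arrays as true spreads, which can overstate differences between groups. Leaving out single arrays gave 1804 without DN-MCU adult 2, 2214 without DN-MCU adult 3, 658 without WT adult 2 and 619 without WT adult 3, the neonatal replicate block gave 636 and array weights 2036. Of 33 gene lists 15 passed, 6 higher and 9 lower, none with an estimated correlation and 13 by fry.

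The same comparison in neonatal hearts gave few calls. Chac1, a glutathione-degrading enzyme of the stress response, rose from 2.99 to 7.54 (4.55, SE 0.54, adjusted p = 0.04), the centrosomal gene Cep72 rose from 3.00 to 4.03 (1.04, SE 0.13, adjusted p = 0.0414), and Gsg1 fell from 3.86 to 2.23 (-1.63, SE 0.19, adjusted p = 0.04). The lower group of each of these 3 lies under 3.35, near background, so the sizes of these changes are uncertain. Trib3 (3.06, SE 0.43), Asns (2.74, SE 0.40) and Mthfd2 (2.36, SE 0.34) lay above WT without passing (adjusted p = 0.0757 for each). Of the 34 stress list members 1 rose over all probe sets and 10 adjusted over the list alone, with a median of 0.44 (camera adjusted p = 1.36e-27; adjusted p = 0.0551 with an estimated correlation). No other of the 33 lists passed as higher.

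The remaining lists that passed in neonates were lower and consisted mostly of markers of particular tissues and cells. The 13 atrial markers had a median of -0.69 (camera adjusted p = 5.18e-17; adjusted p = 0.0715 with an estimated correlation). None passed singly in limma and 1 fell adjusted over the list alone; Sln, the sarcolipin gene, lay at -1.69 (SE 0.41, adjusted p = 0.855), Fgf12 at -1.77 (SE 0.59), Mybphl at -1.40 (SE 0.52) and Bmp10 at -0.82 (SE 0.27). The 12 epicardial and mesothelial markers had a median of -0.78 (adjusted p = 4.78e-08; adjusted p = 0.142 with an estimated correlation), with Upk3b at -1.31 (SE 0.50) and Bnc1 at -1.08 (SE 0.44). Medians were -0.83 for 6 erythroid markers (adjusted p = 3.77e-05), among them Alas2 at -1.20 (SE 0.51), -0.27 for 16 macrophage markers (2.16e-07) and -0.21 for 8 neutrophil and mast cell markers (0.00229), among them Cma1 at -1.42 (SE 0.35). The adjusted p with an estimated correlation was 0.0783, 0.0783 and 0.163. Smaller medians belonged to ion channels (-0.11, 22 members, adjusted p = 0.00229), the interferon response (-0.04, 22 members, 0.00242), cytosolic calcium handling (-0.03, 51 members, 0.0182), immediate early genes (-0.18, 26 members, 0.0315), hypertrophy genes (-0.02, 22 members, 0.0364) and neuronal and Schwann cell markers (-0.11, 10 members, 0.0464). With an estimated correlation their adjusted p were 0.0869, 0.285, 0.142, 0.762, 0.605 and 0.154. As fixed, the ion channel, calcium handling and hypertrophy lists share members with the atrial list, such as Kcnj3, Sln and Nppa. Whether their lower medians repeat the atrial one was not tested. In these lower lists no member passed over all probe sets (limma; 578 of all probe sets had an unadjusted p under 0.05), and adjusted over the list alone 1 member of the atrial, interferon, and neutrophil and mast cell lists each fell and none of the others passed. Without WT neonate 2 the median was -0.41 for erythroid, -0.43 for epicardial and -0.04 for neutrophil and mast cell markers, the last no longer passing (adjusted p = 0.0912); this last median was -0.14 without DN-MCU neonate 2 and -0.50 without WT neonate 3, and that of the ion channels was -0.06 without WT neonate 3. The interferon list did not pass without DN-MCU neonate 3 (adjusted p = 0.0537), the calcium handling list without DN-MCU neonate 1 (0.104) or WT neonate 3 (0.0869), and the immediate early list without DN-MCU neonate 1 (0.694), WT neonate 1 (0.143) or WT neonate 3 (0.109). The interferon median was -0.01 without DN-MCU neonate 3 and -0.06 without WT neonate 2. For calcium handling it was -0.02, -0.05 and -0.06 without DN-MCU neonates 1, 2 and 3. The immediate early median was -0.11 without DN-MCU neonate 1 or WT neonate 3. The hypertrophy list, whose median lay between -0.08 and 0.07 with single arrays left out, did not pass without DN-MCU neonates 1 or 3 (0.889 and 0.0548) or WT neonates 2 or 3 (0.102 and 0.195), nor with neonates fitted alone (0.212). With single neonatal arrays left out, the neuronal list passed only without DN-MCU neonate 1. The actin 3′ minus 5′ signal, a measure of RNA quality, was 1.43, 1.56 and 1.28 in DN-MCU neonates 1 to 3 and 1.07, 1.5 and 1.03 in WT neonates 1 to 3, higher in DN-MCU within each number. The same measure for Gapdh was -0.40, -0.20 and -0.53 in DN-MCU and -0.51, -0.18 and -0.49 in WT neonates 1 to 3. It was higher in DN-MCU for number 1 and lower for numbers 2 and 3. Xist, expressed from the inactive X chromosome, was high in DN-MCU neonates 2 and 3 (10.17 and 10.08) and WT neonate 3 (10.38) and between 2.58 and 2.84 in the other 9 arrays, so the neonatal groups held different numbers of arrays with Xist. With the Xist signal as a covariate, an alternative chosen after the data were seen, the median was 0.47 for the stress list, -0.85 for the atrial and -0.69 for the epicardial list, the neuronal list no longer passed (adjusted p = 0.126) and no single probe set passed in limma.

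Genes named by rank that did not pass in neonates were Vsnl1 (-2.31, SE 0.40, adjusted p = 0.215), Rd3 (-1.28, SE 0.25), Adm (-1.06, SE 0.21) and Rxfp1 (-0.66, SE 0.14). Nppa (-0.25, SE 0.16), Nppb (-0.03, SE 0.30), Myh6 (-0.08, SE 0.11) and Myh7 (0.09, SE 0.50) did not pass either. In all, 4 of 24176 probe sets passed, 3 higher and 1 lower, namely those of Mcu, Chac1, Cep72 and Gsg1, and 12.6% of probe sets showed no overlap between groups (chance 10%). The count was 0 without DN-MCU neonate 1 or WT neonate 2, 2 without DN-MCU neonate 2 and 12 without DN-MCU neonate 3, 1, the Mcu probe set, with neonatal arrays fitted alone, and 95 with array weights. Whether the replicate number pairs the neonatal arrays is not established. With that number as a block the count was 0, Chac1, Cep72 and Gsg1 had an adjusted p of 0.0791 each, and the immediate early list had 0.0593. Chac1 and Cep72 passed only without DN-MCU neonate 3 (adjusted p = 0.0329 each) among the fits that left out 1 neonatal array, and Gsg1 only without WT neonate 3 (0.00943). Of the 33 lists 12 passed, 1 higher and 11 lower, none with an estimated correlation and 1, the stress list, by fry (adjusted p = 0.0369).

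Whether the effect of DN-MCU differed between ages was tested as the adult effect minus the neonatal effect. Stress response genes rose more in adults: the difference was 4.84 (SE 0.48) for Mthfd2, 5.01 (SE 0.49) for Slc7a5, 3.81 (SE 0.56) for Asns and 3.25 (SE 0.31) for Psat1. Of the 34 stress list members 9 had a larger effect in adults and none a smaller one, or 15 and 1 adjusted over the list alone, with a median difference of 0.82 (camera adjusted p = 1.73e-14; adjusted p = 0.134 with an estimated correlation). The smallest p values belonged to Shisa3 (5.03, SE 0.24), Avil (4.61, SE 0.31), the mitochondrial creatine kinase Ckmt1 (4.13, SE 0.29), Pcbd1 (3.47, SE 0.26) and Brca2 (5.82, SE 0.46). In the other direction they belonged to the integrin subunit Itgb6 (-2.00, SE 0.17), Magix (-2.38, SE 0.21), Pdzd3 (-3.17, SE 0.39), B330016D10Rik (-2.04, SE 0.26) and Ano10 (-2.81, SE 0.38). At least 1 group of Avil, Ckmt1, Brca2, Itgb6, Magix, Pdzd3 and B330016D10Rik lay under 3.35, near background.

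Fatty acid genes were lower in adult DN-MCU hearts relative to the neonatal effect, with a median difference of -0.49 over 47 members (adjusted p = 8.91e-09; adjusted p = 0.134 with an estimated correlation), and 1 of them, Ehhadh (-1.50, SE 0.29), passed, also adjusted over the list alone. Single members of other lists that passed were Ern1 (1.43, SE 0.26), Srxn1 (1.41, SE 0.26), Acta2 (1.61, SE 0.29), Myc (1.95, SE 0.26) and, in the other direction, Nqo1 (-1.22, SE 0.20). With the neonatal replicate block Ehhadh (adjusted p = 0.164), Ern1 (0.103), Nqo1 (0.0763), Srxn1 (0.12) and Acta2 (0.119) did not pass. In all, 190 probe sets passed, 142 with a more positive effect in adults and 48 with a more negative one. The count was 347 without DN-MCU adult 2, 636 without DN-MCU adult 3, 113 without WT adult 2, 108 without WT adult 3, 70, 117 and 95 without DN-MCU neonates 1, 2 and 3, 75 without WT neonate 1 or 2 and 82 without WT neonate 3, 71 with the neonatal replicate block and 1216 with array weights. Of the 33 lists 16 passed, 7 more positive and 9 more negative in adults, none with an estimated correlation (adjusted p of 0.134 or more) and 6 by fry.

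**Figure D3:**
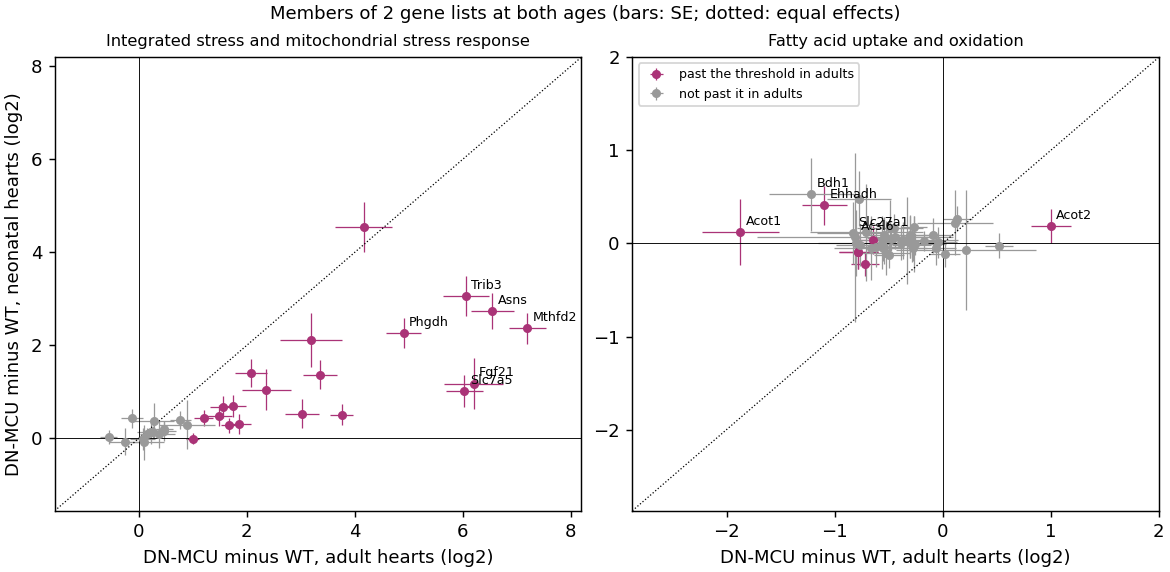
DN-MCU minus WT in adult hearts (horizontal axis, log2) against neonatal hearts (vertical axis, log2) for each measured member of the stress response list (left, 34 genes) and of the fatty acid list (right, 47 genes); points are log2 differences of 3 against 3 arrays, bars are SE and the dotted line marks equal effects. Most stress genes that passed in adults lie below the dotted line, such as Mthfd2 at 7.20 and 2.36, and most fatty acid genes lie left of 0 in adults and near 0 in neonates.

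The effect averaged over both ages drew on 6 DN-MCU and 6 WT hearts. The Mcu probe set that rose (5.975, SE 0.364) lies outside the ranking that follows, because the other Mcu probe set stands for the gene. The largest rises were those of Mthfd2 (4.78, SE 0.24), Asns (4.64, SE 0.28), Trib3 (4.56, SE 0.30), Chac1 (4.36, SE 0.38), the cationic amino acid transporter Slc7a3 (3.94, SE 0.35), Fgf21 (3.69, SE 0.38), Phgdh (3.59, SE 0.23), Slc7a5 (3.53, SE 0.24), the mitochondrial folate enzyme Aldh1l2 (2.66, SE 0.41) and the transcription factor Atf5 (2.36, SE 0.22). Of the genes of this paragraph Slc7a3, Fgf21, Vsnl1 and Gdap10 and, in WT neonates, Chac1 had groups under 3.35, near background, so their rank by size is uncertain. Of the 34 stress list members 20 rose and none fell, or 22 and 0 adjusted over the list alone, with a median of 0.99. This was the only list in any of the 5 comparisons that also passed with an estimated correlation (camera adjusted p = 4.7e-29; adjusted p = 0.047 with an estimated correlation). Genes lower on average at both ages were Sln (-1.52, SE 0.29), Vsnl1 (-1.40, SE 0.28), Kcnj3 (-1.33, SE 0.26), an atrial potassium channel subunit, Maob (-1.20, SE 0.17), a monoamine oxidase, and, by smaller amounts between -0.70 and -0.89, Adamts3, Pkia, Gdap10, Mlf2, Med12l and Reln. Sln and Kcnj3 were the 2 of 13 atrial markers that fell (3 adjusted over the list alone), and that list's median was -0.36 (adjusted p = 0.00052; adjusted p = 0.299 with an estimated correlation), or -0.17 without DN-MCU neonate 3.

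Other genes that passed in the average were Krt18 (1.51, SE 0.30), Ccnd2 (1.08, SE 0.20), Myc (1.49, SE 0.13), Ern1 (0.62, SE 0.13) and Atf6 (0.54, SE 0.10), which rose, and Hadha (-0.47, SE 0.09), which fell. With the neonatal replicate block Kcnj3 (adjusted p = 0.0513), Med12l (0.0576), Pkia (0.0648), Reln (0.107), Atf6 (0.0766), Ccnd2 (0.0778), Hadha (0.0926), Ern1 (0.093) and Krt18 (0.101) did not pass. In all 444 probe sets passed, 318 higher and 126 lower. The count was 719 without DN-MCU adult 2, 936 without DN-MCU adult 3, 264 without WT adult 2, 271 without WT adult 3, 251, 222 and 261 without DN-MCU neonates 1, 2 and 3, 183 without WT neonate 1 and 192 without WT neonate 3, 212 with the neonatal replicate block and 1735 with array weights. Of the 681 probe sets that rose in adults 502 (73.7%) lay above WT in neonates, with a median of 1.25 in adults and 0.12 in neonates, and of the 471 that fell 274 (58.2%) lay below WT in neonates; the 2 effects share no arrays. Of the 33 lists 16 passed, 4 higher and 12 lower, 1 of them with an estimated correlation and 5 by fry.

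WT hearts also changed with age, with neonates set against adults. Neonatal hearts held far more transcript of Tnni1, the slow skeletal troponin I of the immature heart (11.99, SE 0.11, with the adult group at 2.13, near background), of Cited1 (8.27, SE 0.36) and Nrk (7.93, SE 0.20), and of the mitotic genes Cdca8 (7.37, SE 0.48), Ccnb2 (7.28, SE 0.62), Ube2c (7.21, SE 0.58), Birc5 (6.97, SE 0.73) and Ccna2 (6.76, SE 0.49). Bex4 and Vash2 rose by 7.25 and 7.08. Adult levels of Cited1, Cdca8, Ccnb2, Birc5 and Vash2 and neonatal levels of Adipoq, Cyp2e1 and Cpxm2 also lay under 3.35. Myh7, the slow myosin heavy chain, was higher by 3.40 (SE 0.50), while Myh6 did not pass (-0.27, SE 0.11, adjusted p = 0.0614, with other probe sets of opposite sign). Lower in neonates were the adipocyte hormone gene Adipoq (-8.46, SE 0.60), Cyp2e1 (-8.09, SE 0.44), Art1 (-7.63, SE 0.28), the muscle ribosomal protein gene Rpl3l (-7.62, SE 0.67), the airway secretory gene Scgb1a1 (-7.36, SE 1.80), Tuba8 (-7.26, SE 0.37), Myot (-7.16, SE 0.79), Cpxm2 (-7.12, SE 0.45), Ces1d (-6.95, SE 0.36) and Car3 (-6.87, SE 0.68).

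Lists that were higher in neonates were led by the cell cycle, with 41 of 42 members higher (also adjusted over the list alone), among them the mitotic kinases Aurka (5.31, SE 0.22) and Plk1 (4.66, SE 0.20), and a median of 4.64 (adjusted p = 2.85e-17; adjusted p = 0.152 with an estimated correlation). Epicardial markers had 8 of 12 members higher and a median of 2.00 (adjusted p = 0.00286), neutrophil and mast cell markers 6 of 8, S100a8 among them (4.94, SE 0.48), and 2.58 (0.0152), and extracellular matrix genes 20 of 38 higher and 5 lower, Fbn2 among them (6.74, SE 0.32), and 0.78 (0.0223). Adjusted over the list alone 8, 6 and 21 rose and 0, 0 and 5 fell, and the adjusted p with an estimated correlation was 0.282, 0.224 and 0.539. Without WT adult 2 the extracellular matrix list did not pass (adjusted p = 0.0575).

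Mitochondrial and contractile lists were lower in neonates. Of 32 complex I subunits 19 fell (24 fell and 1 rose adjusted over the list alone; median -0.41, adjusted p = 1.21e-06; adjusted p = 0.224 with an estimated correlation). Of 47 fatty acid genes 23 fell and 6 rose (25 and 7 adjusted over the list alone; median -0.53, adjusted p = 9.08e-05; adjusted p = 0.189 with an estimated correlation), with Bdh1 (-5.30, SE 0.39) and Acad11 (-3.31, SE 0.19) falling and Cpt1a (1.64, SE 0.14) and Fabp5 (1.99, SE 0.14) rising. Of 25 tricarboxylic acid cycle genes 12 fell, also adjusted over the list alone (median -0.35, adjusted p = 8.75e-06; adjusted p = 0.0841 with an estimated correlation), Got1 among them (-1.74, SE 0.15). Of 43 subunits of complexes II to V 13 fell and 3 rose, also adjusted over the list alone (median -0.21, adjusted p = 0.000691; adjusted p = 0.224 with an estimated correlation). The adult muscle forms Cox7a1 (-1.40, SE 0.14) and Cox6a2 (-1.25, SE 0.14) fell, and Cox6a1 (0.94, SE 0.13) and Atpif1 (1.42, SE 0.14) rose. Of 25 sarcomere genes 14 fell (16 adjusted over the list alone; median -0.45, adjusted p = 1.41e-07; adjusted p = 0.152 with an estimated correlation), with Tcap at -3.46 (SE 0.16) and Ckmt2 at -3.53 (SE 0.22). In the list of mitochondrial calcium transport 9 of 21 genes fell and 2 rose, also adjusted over the list alone (median -0.43, adjusted p = 0.00756; adjusted p = 0.152 with an estimated correlation). These included Slc8b1 (-1.48, SE 0.21), Ppif (-1.24, SE 0.17) and Mcur1 (-0.67, SE 0.12), which fell, and Slc25a24 (1.96, SE 0.29), which rose. Without WT neonate 1 the median of this list was -0.28. Nppa (-0.44, SE 0.16), Atp2a2 (-0.47, SE 0.11) and Pdk4 (-0.93, SE 0.24) were also lower.

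Lists of the interferon response, macrophages, the clock and adipocytes were lower too. Of 22 interferon response genes 16 fell (median -1.49, adjusted p = 2.14e-08; adjusted p = 0.0841 with an estimated correlation), Psmb8 among them (-3.33, SE 0.18), and of 16 macrophage markers 11 fell (median -2.08, adjusted p = 3.39e-07; adjusted p = 0.0841 with an estimated correlation), C1qa among them (-2.73, SE 0.17). Of 18 clock genes 12 fell and 3 rose (median -1.22, adjusted p = 0.000596; adjusted p = 0.0841 with an estimated correlation). The clock output genes Dbp (-3.74, SE 0.24), Tef (-3.47, SE 0.12) and Ciart (-5.04, SE 0.30) fell and Npas2 rose (3.32, SE 0.28). Of 10 adipocyte markers 7 fell (median -3.61, adjusted p = 0.000198; adjusted p = 0.224 with an estimated correlation). Adjusted over the list alone the counts were the same in these 4 lists except that 1 macrophage marker rose. Other lists that passed were heat shock chaperones (10 of 20 fell, median -0.51), antioxidant genes (14 of 31 fell and 5 rose, -0.21), glycolysis (17 of 32 fell and 7 rose, -0.42), pyruvate entry (7 of 13 fell and 1 rose, -0.82) and mitochondrial biogenesis (7 of 31 fell and 3 rose, -0.27). Their camera adjusted p was 0.000429, 0.00512, 0.00512, 0.00555 and 0.0418, and the adjusted p with an estimated correlation was 0.152, 0.224, 0.406, 0.224 and 0.152. The antioxidant median was -0.12 without WT adult 1, and the biogenesis list did not pass without WT adult 2 (adjusted p = 0.06), WT adult 3 (0.0632) or WT neonate 1 (0.0517). Adjusted over the list alone 11, 14, 17, 7 and 6 fell and 0, 5, 7, 1 and 2 rose.

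In all 10899 probe sets passed between WT neonates and adults, 5909 higher in neonates and 4990 lower, and 65.5% of probe sets showed no overlap between groups (chance 10%). Leaving out any 1 array gave between 8826 and 10181 calls, and subtracting array medians shifted the median of all probe sets from 0.07 to 0.20 and the share of calls that were higher from 54.2% to 62.5%. All adults were labelled male and the sex of neonates is not given in the labels, so age and sex are not fully separated here. Some array measures also parted the ages: the spiked controls averaged between 10.46 and 10.58 in neonates and between 11.14 and 11.72 in adults, and the actin 3′ minus 5′ signal was between 1.03 and 1.56 in neonates and between 0.77 and 0.90 in adults, which this comparison cannot separate from age. The Gapdh 3′ minus 5′ signal overlapped, between -0.53 and -0.18 in neonates and between -0.57 and -0.38 in adults. Of the 33 lists 19 passed, 4 higher and 15 lower, none with an estimated correlation and 28 by fry.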

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

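Among the tests in this part, those of other cell types, of the transgene signal, of 1 array as the whole source and of the atrial share were chosen after the results were seen. A test of the difference of effects picked out 190 probe sets whose response to DN-MCU differed between ages. Among 100 splits of the same arrays, drawn at random with the real one included, 7 gave a count as large, the highest being 286, so chance cannot be excluded for this count. The 6 others as large all kept WT and DN-MCU adults apart and mixed only the neonatal genotypes, as did 4 more, with counts from 156 to 286. The 89 splits that mixed the adult genotypes gave between 0 and 14. The count therefore rests on the adult genotypes and does not separate real from mixed neonatal ones. For lists 5 of 100 splits gave a count as large as the 16 found, and none of the 16 passed with an estimated correlation (adjusted p of 0.134 or more); 7 of the 16 passed whichever array was left out.

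Genes picked out by that test with a more positive effect in adults were Brca2 (5.82), Shisa3 (5.03), Slc7a5 (5.01), Mthfd2 (4.84), Avil (4.61), Ckmt1 (4.13), Asns (3.81), Pcbd1 (3.47), Psat1 (3.25), Myc (1.95), Acta2 (1.61), Ern1 (1.43) and Srxn1 (1.41). Those with a more negative effect were Pdzd3 (-3.17), Ano10 (-2.81), Magix (-2.38), B330016D10Rik (-2.04), Itgb6 (-2.00), Ehhadh (-1.50) and Nqo1 (-1.22). The lists picked out had median differences of 0.82 (stress response), 0.59 (atrial), 0.57 (immediate early), 0.33 (endoplasmic reticulum stress), 0.31 (hypertrophy), 0.21 (antioxidant) and 0.20 (heat shock). More negative were those of fatty acid genes (-0.49), pyruvate entry (-0.40), the circadian clock (-0.30), endothelial markers (-0.28), the tricarboxylic acid cycle (-0.27), cytosolic calcium handling (-0.26), complex I (-0.24), complexes II to V (-0.15) and the sarcomere (-0.13). Leaving out 1 array moved some of these medians by over 1.5 times. The atrial one moved to 0.30 without DN-MCU neonate 3 (adjusted p = 0.058), hypertrophy to 0.10 without DN-MCU neonate 1 and heat shock to 0.44 without DN-MCU adult 3. Pyruvate entry moved to -0.22 without WT adult 2 and the clock to -0.14 without DN-MCU adult 3 (0.114). Calcium handling moved to -0.15 without DN-MCU adult 1 (0.0509) and -0.12 without DN-MCU adult 3 (0.0681), and the sarcomere to -0.06 without DN-MCU neonate 2 (0.0526) and -0.07 without WT adult 3. The atrial, hypertrophy, antioxidant, heat shock, pyruvate entry, clock, calcium handling, complex II to V and sarcomere lists each did not pass without at least 1 of the arrays.

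Xist was picked out as a signal outside the comparisons: it was 10.17 in DN-MCU neonate 2, 10.08 in DN-MCU neonate 3 and 10.38 in WT neonate 3.

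The first pattern weighed is the higher stress response in adult DN-MCU hearts, with a list median of 1.52. Without DN-MCU adult 3, the array farthest from the others, it was 1.53 (SE 0.11), which excludes that array as the source. Among adults of the higher range of animal numbers (2 against 2) it was 1.46 (SE 0.03), so the rise does not rest on the pair of lower number. Each range held equal numbers of both genotypes. A difference between the ranges could therefore not have produced the rise by itself, whatever this value. The highest median among cell type lists was 0.0889 (macrophage markers, SE 0.0972), but the adipocyte median of -0.58 (SE 0.87) is too uncertain to settle whether RNA from another cell type contributes. An effect of the mutant protein, of expressing any transgene or of where it inserted remains open, since no control transgene is among these samples.

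The second pattern is that these genes rise less in neonates, with a median difference of 0.82. Within DN-MCU hearts the Mcu probe set that rose was 0.82 higher in adults (SE 0.51), which leaves open both an equal transgene signal and one 2 times lower in neonates. Without DN-MCU adult 3 the median difference was 0.87 (SE 0.24), and the number of probe sets picked out went from 190 to 636. A 95% interval of 0.87 with that SE starts at 0.295, above 0. That SE is of the mean over members, so the interval is only approximate for the median. Mean stress scores were 2.28 and 2.04 in DN-MCU adults 1 and 2 and 0.79, 1.23 and 0.56 in DN-MCU neonates 1 to 3. These values argue against that array as the whole source. A limit of 0.41 by 2 SE, computed from the observed 0.82 by a rule written before the test, was not met. A part played by that array therefore stays open. With the Xist covariate the neonatal median was 0.47 (SE 0.24), below the midpoint of 0.98 between the ages by over 2 SE. The rule was written before the test, but the midpoint comes from the observed medians. The fit with the covariate has few arrays and takes the DN-MCU effect as equal in both sexes. It therefore speaks only against a shift with Xist shared by both genotypes, and mixed sex is not excluded. A true effect of age or of the time since the transgene was first expressed cannot be told apart here.

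The third pattern is the lower atrial markers in DN-MCU neonates, with a median of -0.69. Of the 13 measured markers 92.3% were lower, which restates the call of the list and decides nothing between a smaller share of atrial tissue and lower expression within atrial cells. With the Xist covariate the median was no smaller, -0.85, but its error (SE 0.40) is too large to exclude mixed sex, for which the median had to lie beyond -0.35 by 2 SE. The scores differed widely between DN-MCU neonates (-0.74, -0.24 and -1.33).

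Other counts were set against splits of the same arrays too. For probe sets, 1 of 10 splits was as large in adults (highest other 192), 3 of 10 in neonates (highest 8), 1 of 100 for the average of both ages (real 444, highest other 364, among splits that kept the adult genotypes apart) and 1 of 10 for age (highest other 0). With 10 splits the smallest possible share is 0.1. Among the 4 neonatal splits that part all 3 numbered pairs, the real one gave 4 probe sets and the others 1, 0 and 0, and for lists 12 against 12, 11 and 5. The split with 8 parts 1 pair. With only 4 splits, and possible pairs inferred from the same arrays, this adds no support to the neonatal calls. For lists, 1 of 10 was as large in adults (highest other 14), 2 of 10 in neonates (highest other 12), 5 of 100 for the average (highest 18) and 1 of 10 for age (highest other 18). The medians over all splits, the real one included, were 6.5 lists in adults and neonates, 7 for the difference, 6.5 for the average and 15.5 for age. By these splits chance cannot be excluded for the number of lists in any comparison. With only 10 splits each, it cannot be excluded for the probe sets of adults, neonates and age either.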

How the results depend on the processing

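The fits without 2 arrays, with covariates, with the neonatal block, without the pair of adults of lower animal number, and the fit of only the groups compared for lists and genes were chosen after the data were seen. No named gene or list reversed while called in the settings run for it, and the causes of the changes below were not tested. Counts are probe sets, in the order adults, neonates, difference, average and age, with 1152, 4, 190, 444 and 10899 as reported; only counts that moved by over 1.5 times are given. Quantile normalization gave 2 in neonates, subtraction of medians 1, leaving out cross-matching probe sets 2. The stricter filter, which tests fewer probe sets, gave 2 in neonates and 6650 for age, and 1 probe set per gene gave 662 in adults, 268 in the average and 5362 for age. An adjusted p under 0.10 gave 1830, 12, 304 and 705, and an unadjusted p under 0.01 with 1.5-fold gave 1787, 117, 846 and 714. The model without moderation gave 2 in neonates and 124 for the difference, array weights 2036, 95, 1216 and 1735, and the animal number term 1 in neonates. Only the groups compared gave 112 and 1. Without the 2 arrays of lowest weight the counts were 3140, 1, 1112 and 1598, with the Xist covariate 0 in neonates, 94 and 262, with the spike covariate 2 in neonates and 329, and without that adult pair 2 in neonates.

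The replicate number as a block within each age gave 568, 0, 39 and 143. Adult arrays of the same number correlated at -0.381, 0.41 and -0.428, which gave no sign that adult numbers pair them. The block among neonates alone gave 636, 0, 71 and 212 and, beyond the values given in the report, changed no other call. Leaving out each array gave 619 to 2214 in adults, 0 to 12 in neonates, 70 to 636 for the difference, 183 to 936 for the average and 8826 to 10181 for age. For lists the ranges were 11 to 14, 8 to 11, 12 to 18, 12 to 18 and 17 to 20. Of the 15, 12, 16, 16 and 19 lists, 9, 6, 7, 9 and 17 passed whichever array was left out. With an estimated correlation 0, 0, 0, 1 and 0 lists passed, and by fry 1 in neonates, 6 for the difference and 5 for the average. Without that adult pair 9 lists passed in the average.

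Of 184 gene results 110 stayed on their side of the threshold in every setting. Of the 54 adult genes 29 passed whichever array was left out, of the 3 neonatal genes 0, of the 20 for the difference 14, of the 26 for the average 13 and of the 49 for age 48.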

Other observations

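All values in this part were chosen after the data were seen, and none was tested. DN-MCU adult 3 differed from the other DN-MCU adults in several lists: adipocyte markers averaged -2.40, heat shock chaperones -0.72, cell cycle genes -0.64 and neutrophil and mast cell markers -0.58, while erythroid markers averaged 0.93 and skeletal muscle markers 0.41. Its stress list differed by -0.09 and its fatty acid list by 0.10. WT adult 1 held more epicardial (1.25), adipocyte (0.79), extracellular matrix (0.55) and fibroblast (0.44) signal than the other WT adults. These are averages of 1 array against 2.

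Stress scores, relative to the WT mean of the same age, were 2.28, 2.04 and 2.08 in DN-MCU adults 1 to 3 and 0.79, 1.23 and 0.56 in DN-MCU neonates 1 to 3. Within the lower (1 against 1) and higher (2 against 2) range of adult animal numbers, the DN-MCU effect was 7.04 and 7.28 for Mthfd2, 6.12 and 6.76 for Asns, 5.99 and 6.31 for Fgf21 and 5.85 and 6.16 for Trib3, but -6.34 and -2.94 for Myot. Across all probe sets the adult and neonatal effects correlated at r = 0.251, a description only, since probe sets are not independent. The Y-linked gene Eif2s3y lay between 3.20 and 3.32 in the 3 neonatal arrays with high Xist and between 5.61 and 7.32 in the other 9 arrays.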
